A study of Homo sapiens with 12 samples.

How the data were processed

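The series compares HCT116 colorectal carcinoma cells (passages under 15, per the labels) with and without knockout of PPM1G in 4 groups of 3 libraries: 4sU-seq and RNA-seq, each of Ctrl and KO. Per the labels, 4sU-seq cells were seeded as biological replicates, pulsed for 10 min with 500 µM 4sU, and 300 µg of RNA was biotinylated and pulled down; ERCC spike-in RNA was added to every library, at an amount that is not stated. The part of the protocol used here does not describe the RNA-seq cultures, does not say whether the assays shared cultures, and does not say whether the KO cells are a clone or which site was edited.

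The authors deposited 2 tables, 1 per assay, of raw gene counts with 56104 gene IDs and 92 ERCC species. Per the submitters' processing notes, reads were checked with FastQC 0.11.2, aligned to hg38 with HISAT2 2.1.0, handled with SAMtools 1.3 and counted with featureCounts (version not given). The annotation, the counting feature, the strand setting and the treatment of reads with several alignments are not given in the sources used here, nor is it given whether both tables were counted alike. The deposited counts were whole numbers, as tested on the tables. Gene symbols and types were those of the deposited tables. Gene coordinates came from GENCODE 29 on hg38, which matched 52890 of the gene IDs (94.3%) and may not be the annotation the authors used. IDs on alternate loci, such as those of KRT20, KRT23 and HLA-DRA, have no coordinates there.

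Each assay was fitted alone. ERCC counts were left out of the library sizes, genes were kept by filterByExpr (minimum count 10), libraries were scaled by TMM, and KO was compared with Ctrl by the quasi-likelihood F test of edgeR 4.0.16 (glmQLFit and glmQLFTest, two-sided) with Benjamini-Hochberg adjustment and a threshold of 0.05. CPM values given in the text are normalised by TMM and averaged over 3 libraries. The difference between assays was tested as the interaction of genotype and assay over all 12 libraries and the genes kept in both, with TMM factors set within each assay. ERCC shares were compared by exact permutation. Gene lists were tested with camera (limma 3.58.1) at a preset correlation of 0.01 for lists with at least 5 tested members, adjusted over the lists of a comparison, and again with an estimated correlation and with fry. The 32 lists hold 843 entries, 782 of them in the tables. For each list the members that rose or fell were counted over all genes tested and adjusted over the list alone. DESeq2 1.42.0, R 4.3.3, Python 3.11.15 and matplotlib 3.10.9 were also used.

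The tests, lists, alternatives and the rule for named genes were fixed before the data were examined. Named genes are PPM1G; the 8 highest and the 8 lowest log2 fold changes per assay among called genes with a mean log2 CPM of at least 2 and no overlap between the groups; from each list with at least 3 called members or a camera call, up to 4 called members with the smallest p, from other lists at most 1; and for the difference between assays the 4 highest and the 4 lowest with a mean log2 CPM of at least 2 in both. Where 5 or fewer members of a list were called, members outside this rule are named too, without values; these and the genes named for list differences between assays were chosen after their values were seen. Some genes that met these rules are not reported here. Where a group had no count, or up to 3 counts, over its libraries, no fold is given. The ratio of 4sU-seq to RNA-seq in Ctrl was taken on CPM plus 0.5, and bootstrap intervals used 1000 draws.

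Alternatives were DESeq2 size factors, ERCC scaling, library size alone, TMM over all 12 libraries, no filter, a mean of at least 50 counts, a replicate block, a block of replicate 1 against 2 and 3, leaving out each library, the DESeq2 Wald test, all 12 libraries in 1 fit and a fold threshold of 0.5 (log2). Added after the data were seen were the removal of each library's trend with gene span, leaving out both 4sU-seq replicates numbered 2, and adding RNA-seq KO replicates 1 and 2 into 1 library. The fits were tested on simulated data with planted changes: of 1.5-, 2- and 4-fold changes, 0%, 23.9% and 97.0% were recovered in 4sU-seq (3 false calls among 20973 genes), 83.6%, 98.5% and 100% in RNA-seq (10 among 19971) and 6.45%, 43.1% and 96.7% for the difference between assays (12 among 15619). The simulated counts were drawn independently for each gene and library, without differences shared by many genes of a library. These rates therefore need not hold for the real libraries. Raw reads were not available, so alignment and counting were not repeated.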

Results

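HCT116, a colorectal carcinoma cell line, was compared with and without a knockout of PPM1G, which encodes a nuclear serine/threonine phosphatase of the metal-dependent PPM family. Newly made RNA was measured by 4sU-seq, in which cells take up 4-thiouridine during a pulse of 10 min and the labelled RNA is biotinylated and pulled down, and steady-state RNA was measured by RNA-seq. Each assay held 3 control (Ctrl) and 3 PPM1G knockout (KO) libraries, 12 in all. The 4sU-seq libraries held 101884166, 83785534 and 87046950 gene counts in Ctrl replicates 1, 2 and 3 and 96766516, 79403238 and 84901537 in the KO replicates. The RNA-seq libraries held 42479828, 35154208 and 34042299 in Ctrl and 33920835, 36178838 and 30962756 in KO. At these depths 3 counts, taken as the floor of detection, stand for 0.0294 to 0.0378 CPM (normalised counts scaled to library size) in 4sU-seq and 0.0706 to 0.0969 in RNA-seq. Floors cover counting error only. Log2 changes below are KO over Ctrl and are followed by ± a standard error, with n = 3 libraries per group. This error was derived from the F test, as the size of the change divided by the square root of F. For genes near the floor in a group it can be smaller than the counting error of the change.

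The Ctrl libraries of the assays were first set side by side, to see how pulled-down RNA differs from total RNA. The mitochondrially encoded genes had a median log2 ratio of 4sU-seq to RNA-seq of −1.51 and the cytosolic ribosomal proteins of −0.88, against 0.19 for the 15863 genes tested in both assays. The immediate early genes stood at −0.53. Among protein-coding genes the ratio rose with gene span, from a median of −0.62 under 10 kb to 1.18 above 100 kb (Spearman rho 0.50 across 12072 genes, which are not independent replicates). ERCC spike-in RNA made up 0.0371 ± 0.00775% (SD, n = 3) of gene counts in the Ctrl and 0.0371 ± 0.0170% in the KO libraries of 4sU-seq, and 0.524 ± 0.0422% and 0.559 ± 0.0197% in RNA-seq. A two-sided exact permutation test of the shares gave p = 0.9 and p = 0.4; the smallest p that 3 against 3 libraries allow is 0.1, so it could not have shown a difference at 0.05. Spike-in shares spanned 2.44-fold among the 4sU-seq libraries.

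Nascent RNA came first among the comparisons the series design names: which genes differ between KO and Ctrl in newly made RNA. PPM1G itself fell in the KO cells, from 242, 271 and 235 CPM in Ctrl replicates 1 to 3 to 98.9, 144 and 104 CPM in the KO replicates (log2 −1.11 ± 0.17, adjusted p = 0.00717). Under ERCC scaling its change was −0.93 with adjusted p = 0.196. PXDN, which encodes the basement membrane peroxidase peroxidasin, rose most among genes of at least 4 CPM on average, by 9.32 ± 0.40 on the log2 scale, from 0.0694 to 44.5 CPM. EHF, an epithelial transcription factor of the ETS family, rose by 9.21 ± 0.16, from 0.480 to 285 CPM. SLC15A1, a peptide transporter, rose by 5.42 ± 0.17, CASP4, an inflammatory caspase, by 5.23 ± 0.32, and HKDC1, a hexokinase family member, by 4.89 ± 0.20. The noncoding genes RP11-176N18.2 and RP11-103J17.2 rose by 9.29 ± 0.43 and 9.11 ± 0.34.

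Other genes fell strongly in the nascent RNA of KO cells. ZNF595, a zinc finger gene, fell from 15.4 to 0.0352 CPM (log2 −8.65 ± 0.39) and FGF9, a fibroblast growth factor, from 37.7 to 0.860 CPM (−5.45 ± 0.19). The KO level of ZNF595 lay at the floor of detection, so the size of its change rests on few counts. DACT1, an antagonist of WNT signalling, changed by −4.77 ± 0.22, TNFSF4, the ligand of the OX40 receptor, by −3.74 ± 0.22, and the transcription factor gene GLIS3 by −3.39 ± 0.33, from 274 to 26.2 CPM. The zinc finger gene ZNF831, the noncoding RNA LINC00704 and the neuron navigator NAV3 changed by −5.11 ± 0.22, −4.87 ± 0.14 and −3.27 ± 0.49. The call of NAV3 was lost under ERCC scaling (adjusted p = 0.072). On the hg38 build with GENCODE 29 coordinates, PPM1G (ENSG00000115241) lies on the minus strand of chromosome 2 from 27381194 to 27409687 and PXDN (ENSG00000130508) on the same strand from 1631887 to 1744852. EHF (ENSG00000135373) spans 34621093 to 34661057 on chromosome 11, CASP4 (ENSG00000196954) 104942866 to 104969436 on the same chromosome, ZNF595 (ENSG00000272602) 53285 to 88211 on chromosome 4 and FGF9 (ENSG00000102678) 21671383 to 21704498 on chromosome 13.

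Of 21236 genes tested in 4sU-seq, 4166 (19.6%) were called at an adjusted p below 0.05, 2684 higher and 1482 lower in KO, and 1765 rose and 246 fell by more than 2-fold. Of 14730 protein-coding genes tested 2966 were called, and the 4sU-seq counts of list members below stand against this share. The groups did not overlap for 8157 genes, 38.4% of those tested, where chance gives 10%. The share of calls that were higher, 64.4%, was 93.9% of 716 calls under ERCC scaling and 78.3% of 3958 under library size alone, which moved the median of all genes from 0.05 to 0.27 and 0.14. Without KO replicate 2 the count rose to 11673 genes. It fell to 1322, 1478 and 1710 without Ctrl replicates 1, 2 and 3, and to 1645 and 2784 without KO replicates 1 and 3. Leaving out a library makes its group smaller, and a lower count can follow from that alone. Of the 1322 calls without Ctrl replicate 1, 1312 were also among the 4166. Calls of single genes given below as lost without a library may likewise reflect the smaller group, which was not tested. The S numbers in the titles of the 4sU-seq libraries repeat (S3 for Ctrl replicate 1 and KO replicate 2, S4 for KO replicates 1 and 3), and the labels do not say which libraries were sequenced together. The change also followed gene span, with medians from −0.04 under 10 kb to 0.36 above 300 kb (Spearman rho 0.17 across 14141 genes), and rho was 0.01 without KO replicate 3, 0.08 without KO replicate 1, 0.08 without Ctrl replicate 2, 0.16 without Ctrl replicate 1, 0.24 without Ctrl replicate 3 and 0.36 without KO replicate 2.

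**Figure D1:**
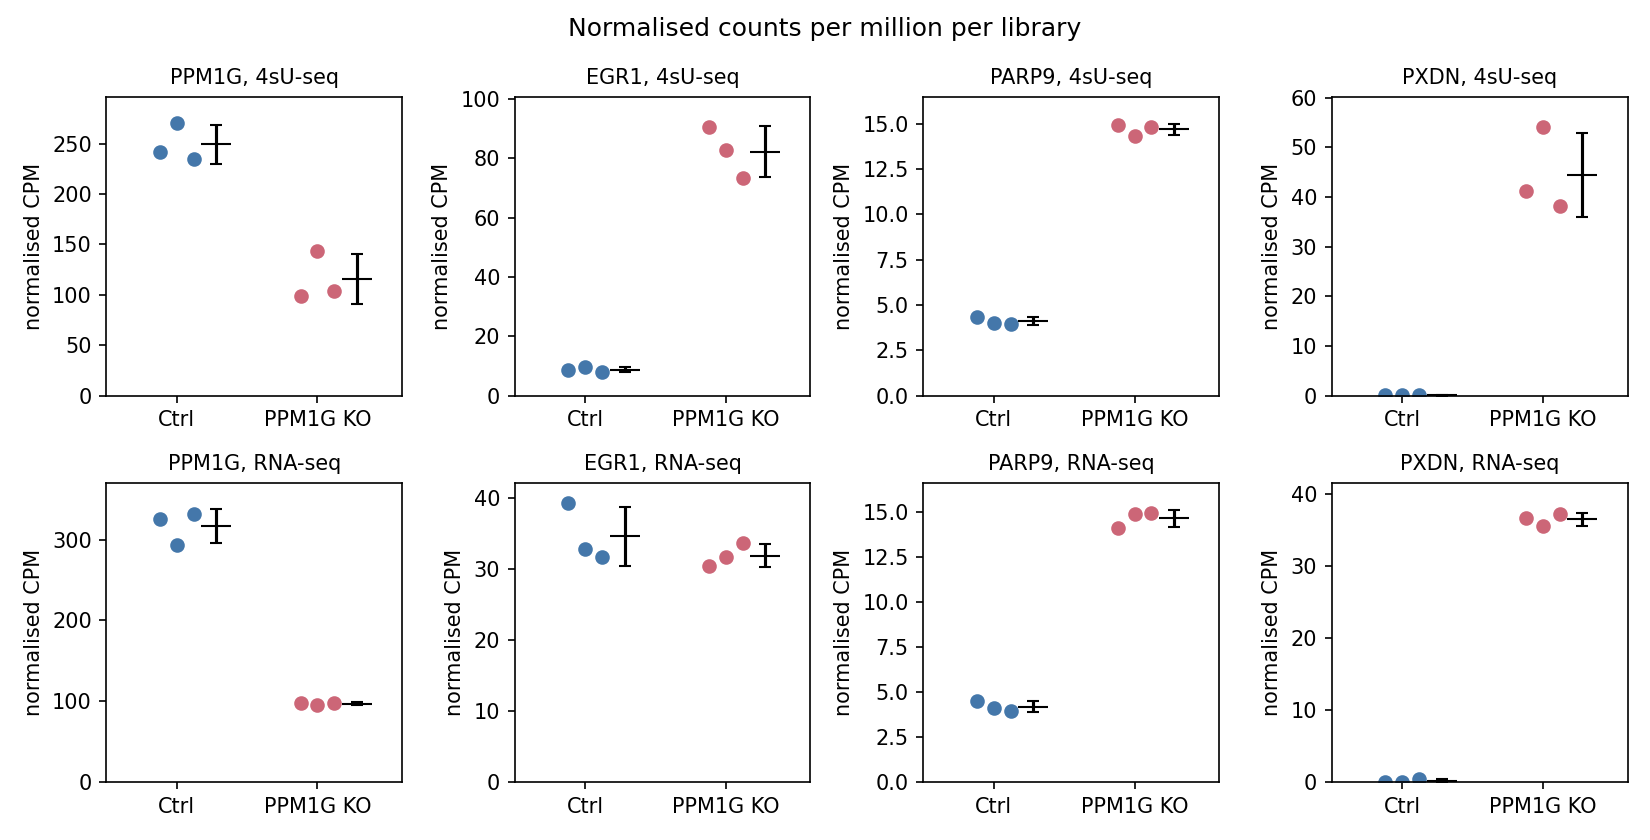
Normalised CPM of PPM1G, EGR1, PARP9 and PXDN in 4sU-seq (upper row) and RNA-seq (lower row); each point is a library and the bar is the mean ± SD of 3. In 4sU-seq the KO libraries lie at 98.9 to 144 CPM for PPM1G against 235 to 271 in Ctrl, and for EGR1 at 73.3 to 90.6 against 8.06 to 9.60, while the RNA-seq groups of EGR1 overlap.

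Signalling genes moved in both directions in nascent RNA. Of 29 measured immediate early genes, which respond within minutes to growth factors and stress, 11 rose, 5 fell and 13 were not called (13 and 5 adjusted over the list alone). EGR1 rose 9.39-fold (log2 3.23 ± 0.14), FOS 7.05-fold (2.82 ± 0.24) and JUN 3.62-fold (1.86 ± 0.22), while FOSL1 fell (−1.42 ± 0.18), as did ZFP36L1, KLF4, KLF6 and DUSP4. The list was called higher by camera (median 0.40, adjusted p = 0.0360; adjusted p = 0.831 with an estimated correlation); that call was lost under library size alone (adjusted p = 0.0568), without Ctrl replicate 1 (0.0541), Ctrl replicate 3 (0.175) or KO replicate 2 (0.357) and with both replicates numbered 2 left out (0.120). Of 23 interferon-stimulated genes 14 rose, 0 fell and 9 were not called (16 and 0 adjusted over the list alone). SAMD9 stood at 2.54 ± 0.25, CMPK2 at 2.17 ± 0.17, the antiviral GTPase MX1 at 1.98 ± 0.16 and PARP9 at 1.84 ± 0.11. Their median was 1.17 (camera adjusted p = 2.05e-08; adjusted p = 0.0823 with an estimated correlation). Of 24 NF-kB and TNF response genes, BIRC3 (2.23 ± 0.36), CXCL8 (2.12 ± 0.38), ICAM1 and LIF rose, and TRAF1 (−0.68 ± 0.13) and TNFAIP3 fell. The other 18 were not called (4 and 2 adjusted over the list alone; camera adjusted p = 0.751). Among 28 p53 target genes 6 rose, 3 fell and 19 were not called (7 and 4 adjusted over the list alone; camera adjusted p = 0.420): the stress cytokine GDF15 rose by 2.81 ± 0.28 and SESN2 by 1.29 ± 0.18, and SPATA18 (−3.33 ± 0.16), the DNA polymerase eta gene POLH (−0.83 ± 0.10) and PLK2 fell. Of the genes given with a value, calls under ERCC scaling remained for EGR1, FOS, JUN, SAMD9, CMPK2, MX1, PARP9, GDF15, SESN2 and SPATA18 and were lost for FOSL1, BIRC3, CXCL8, TRAF1 and POLH (adjusted p from 0.0685 to 0.596). BIRC3 was also lost without Ctrl replicate 1 (0.0559), CXCL8 without KO replicate 1 (0.0553) and TRAF1 without Ctrl replicate 1, Ctrl replicate 2 or KO replicate 1 (0.0628 to 0.0842). The call of ICAM1 was lost under ERCC scaling (0.106) and without Ctrl replicate 1, 2 or 3 or KO replicate 1 (0.0618 to 0.115).

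Among phosphatases of the PPM family, the relatives of PPM1G, PPM1K (0.95 ± 0.17) and PDP1 (0.62 ± 0.11) rose, and PPTC7 (−0.60 ± 0.08) and ILKAP (−0.54 ± 0.09) fell. The other 14 of the 18 were not called (3 and 2 adjusted over the list alone; camera adjusted p = 0.869). In the P-TEFb, 7SK snRNP and pause-release list, whose products regulate the pausing and release of RNA polymerase, AFF4 (0.42 ± 0.11) and HEXIM2 rose. The other 25 of the 27 were not called (0 and 0 adjusted over the list alone; camera adjusted p = 0.923). Within the SMN complex and Sm proteins, which assemble spliceosomal snRNPs, GEMIN5 (−0.60 ± 0.12), GEMIN2 (−0.59 ± 0.13), GEMIN6 (−0.57 ± 0.15) and SNRPD1 (−0.38 ± 0.09) fell. The other 16 of the 20 were not called (0 and 4 adjusted over the list alone). That list was called lower (median −0.30, camera adjusted p = 0.00288; adjusted p = 0.468 with an estimated correlation). SR proteins and their kinases, which regulate splicing, included SRPK1 (−0.56 ± 0.12), SRSF1 (−0.51 ± 0.10) and SRSF7 (−0.47 ± 0.10), which fell. The other 18 were not called (0 and 3 adjusted over the list alone). Their median of −0.20 was called lower (camera adjusted p = 0.0120; adjusted p = 0.365 with an estimated correlation), but turned to 0.06 under ERCC scaling, and the call was lost there (0.108), without KO replicate 2 (0.0519) and with both replicates numbered 2 left out (0.0703). ERCC scaling ended the call of each gene of this paragraph given with a value (adjusted p from 0.224 to 0.923), library size alone those of SNRPD1 and GEMIN6 (0.0870 and 0.0981), and DESeq2 size factors and no filter that of AFF4 (0.0576 and 0.109), which was also lost with the length trend removed (0.0615). Leaving out Ctrl replicate 1, Ctrl replicate 2 or KO replicate 1 ended each of them except that of PPTC7, and leaving out Ctrl replicate 3 or KO replicate 3 ended some (0.0520 to 0.188).

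Cell cycle and ribosome lists followed in nascent RNA. Of 30 G1/S and DNA replication genes 0 rose, 13 fell and 17 were not called (0 and 20 adjusted over the list alone). MCM10 (−0.90 ± 0.11) and CDC45 (−0.81 ± 0.14) were among those that fell. Their median was −0.53 (camera adjusted p = 2.07e-09; adjusted p = 0.468 with an estimated correlation). Among 27 G2/M and mitosis genes 7 fell, 0 rose and 20 were not called (0 and 9 adjusted over the list alone). The mitotic kinase AURKA stood at −0.96 ± 0.15 and the spindle factor TPX2 at −0.65 ± 0.11 (list median −0.49, camera adjusted p = 8.13e-07; adjusted p = 0.196 with an estimated correlation). Ribosome biogenesis genes had a median of −0.48: POLR1B (−0.57 ± 0.10), UTP20 (−0.57 ± 0.12), POLR1A and NPM1 (−0.36 ± 0.08) fell, while GNL3, which encodes nucleostemin, rose (0.58 ± 0.10). The other 20 of the 25 were not called (1 and 5 adjusted over the list alone; camera adjusted p = 2.47e-05; adjusted p = 0.468 with an estimated correlation). Cytosolic ribosomal proteins were called lower as a list (median −0.25, camera adjusted p = 4.52e-05; adjusted p = 0.793 with an estimated correlation), although RPL14 (−0.52 ± 0.14), RPL37 (−0.50 ± 0.09), RPL34 and RPS24 alone fell. The other 50 of the 54 were not called (0 and 3 adjusted over the list alone). Of 41 replication-dependent histone genes HIST1H3E rose (1.19 ± 0.12). The other 40 were not called (1 and 0 adjusted over the list alone; median −0.14, camera adjusted p = 0.219); without KO replicate 2 this list was called lower (median −0.53, adjusted p = 0.000243). Under ERCC scaling the calls of the genes given here with a value were lost (adjusted p from 0.0893 to 0.937), and under library size alone those of NPM1 (0.0629) and RPL14 (0.105). Leaving out single libraries (Ctrl replicate 1, 2 or 3, KO replicate 1 or 3) ended calls of CDC45, TPX2, POLR1B, UTP20, NPM1, GNL3, RPL14 and RPL37 (adjusted p from 0.0507 to 0.172). RPL34 and RPS24 were lost under ERCC scaling (0.818 and 0.862), library size alone (0.0506 and 0.0560) and without any 1 of the same libraries (0.0577 to 0.109).

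Genes of cell identity and adhesion gave large single changes. Mesenchymal genes split: VIM, which encodes the intermediate filament vimentin, fell (−4.38 ± 0.18), while 8 of 17 rose, among them the collagen gene COL3A1 (3.02 ± 0.47) and TWIST2 (2.26 ± 0.34). The other 8 were not called (8 and 1 adjusted over the list alone). The list was called higher (median 0.74, camera adjusted p = 0.0314; adjusted p = 0.365 with an estimated correlation), and that call was lost under ERCC scaling (0.0625), library size alone (0.0566), no filter (0.0533), a mean of 50 counts or more (0.59) and a replicate block (0.155), without KO replicate 2 (0.357) or KO replicate 3 (0.0757), with both replicates numbered 2 left out (0.228) and with the length trend removed (0.113). In the epithelial adhesion list, E-cadherin (CDH1, 1.03 ± 0.11), TJP3 (1.99 ± 0.25), CLDN3 and GRHL2 rose. The other 17 of the 21 were not called (4 and 0 adjusted over the list alone; camera adjusted p = 0.331). KRT20 (1.98 ± 0.17), MUC13 (1.81 ± 0.16), CDH17 and HNF4A rose among 13 intestinal differentiation genes. The other 9 were not called (4 and 1 adjusted over the list alone; camera adjusted p = 0.0791, and 0.0341 with a mean of 50 counts or more). WNT target genes that rose were EPHB2 (1.21 ± 0.11), EPHB3, TNFRSF19, RNF43 and the inhibitor DKK1 (1.08 ± 0.14), while SOX4 fell (−1.16 ± 0.15). The other 11 of the 17 were not called (6 and 1 adjusted over the list alone; camera adjusted p = 0.331). SMAD and BMP response genes went both ways, with ID4 (2.87 ± 0.38), ID2 (2.37 ± 0.17) and SKIL higher and PMEPA1 (−2.12 ± 0.14), TGFBI and SKI lower. The other 10 of the 16 were not called (5 and 4 adjusted over the list alone; camera adjusted p = 0.923). YAP targets were called lower as a list (median −0.34, camera adjusted p = 0.00134; adjusted p = 0.196 with an estimated correlation): F3, which encodes tissue factor, fell by 1.77 on the log2 scale (SE 0.10), and CTGF (−1.04 ± 0.18) and AXL fell too. The other 13 of the 16 were not called (0 and 3 adjusted over the list alone). Among integrins, laminins and basement membrane genes ITGA2 (2.45 ± 0.33), HSPG2, ITGB6 and LAMB1 rose, and AGRN (−1.12 ± 0.20), ITGB5 and LAMA3 fell. The other 15 of the 22 were not called (4 and 3 adjusted over the list alone; camera adjusted p = 0.517). Of the genes given with a value, ERCC scaling ended the calls of CDH1, EPHB2, DKK1, SOX4, F3, CTGF, ITGA2 and AGRN (adjusted p from 0.0519 to 0.226), and CTGF and AGRN were lost without Ctrl replicate 1, Ctrl replicate 2 or KO replicate 1 (0.0548 to 0.0660). Of those named without a value, GRHL2, CDH17, HNF4A, TNFRSF19, TGFBI, AXL, HSPG2 and ITGB5 lost their calls under ERCC scaling (0.0645 to 0.758). These and CLDN3 also lost them without 1 or more single libraries (0.0510 to 0.164), HNF4A, AXL, HSPG2 and ITGB5 with the length trend removed (0.0508 to 0.0956), and AXL and ITGB5 under library size alone (0.0907 and 0.0646).

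Stress and metabolic lists also moved. ATF4 and amino acid stress genes were called higher (median 0.59, camera adjusted p = 0.000126; adjusted p = 0.468 with an estimated correlation), with 11 of 23 rising, 0 falling and 12 not called (12 and 0 adjusted over the list alone). CHAC1, a glutathione-degrading enzyme, rose by 3.49 ± 0.26, asparagine synthetase (ASNS) by 1.28 ± 0.12 and DDIT3, which encodes CHOP, by 1.24 ± 0.14. HERPUD1 (1.11 ± 0.11) and DNAJB9 rose among 16 unfolded protein response genes and 14 were not called (2 and 0 adjusted over the list alone; camera adjusted p = 0.938). Heat shock genes had a median of −0.38 and were called lower (camera adjusted p = 0.00417; adjusted p = 0.468 with an estimated correlation), with DNAJA1 (−0.53 ± 0.09) the 1 of 13 that fell. The other 12 were not called (0 and 4 adjusted over the list alone). Cholesterol synthesis genes were called lower (median −0.38, camera adjusted p = 0.000477; adjusted p = 0.468 with an estimated correlation): TMEM97 (−0.94 ± 0.17), ACAT2 (−0.68 ± 0.12), IDI1 (−0.61 ± 0.16) and NSDHL fell. The other 18 of the 22 were not called (0 and 3 adjusted over the list alone). Of 21 hypoxia and glycolysis genes NDRG1 (1.26 ± 0.17), MXI1 and EGLN3 rose, and hexokinase 2 (HK2, −0.71 ± 0.15) fell. The other 17 were not called (3 and 1 adjusted over the list alone; camera adjusted p = 0.324). AKR1C3 rose (1.54 ± 0.25), TXNRD1 (−0.48 ± 0.07) and GCLM fell and 15 of 18 NRF2 targets were not called (1 and 1 adjusted over the list alone; camera adjusted p = 0.468). None of 15 mitochondrially encoded genes was called (0 and 0 adjusted over the list alone; camera adjusted p = 0.896), with MT-ND6 at 0.19 ± 0.12. PMAIP1, which encodes the BH3-only protein NOXA, rose (1.63 ± 0.17), and BIK (−0.63 ± 0.16) and BCL2L11 fell. The other 15 of the 18 apoptosis regulators were not called (1 and 2 adjusted over the list alone; camera adjusted p = 0.403). ERCC scaling left the calls of CHAC1, DDIT3 and NDRG1 and ended those of the other genes given here with a value (adjusted p from 0.0620 to 0.868). Leaving out Ctrl replicate 1, 2 or 3 or KO replicate 1 or 3 ended calls of DNAJA1, TMEM97, ACAT2, IDI1, HK2, AKR1C3, TXNRD1 and BIK (0.0502 to 0.156), and library size alone those of IDI1 (0.0574) and BIK (0.0863); IDI1 was also lost with the length trend removed (0.0842). Of those named without a value, NSDHL, MXI1, EGLN3, GCLM and BCL2L11 lost their calls under ERCC scaling (0.264 to 0.921) and without 4 or more of the single libraries (0.0592 to 0.181). NSDHL, GCLM and BCL2L11 lost them under library size alone (0.105, 0.0633 and 0.0831), GCLM with a mean of 50 counts or more (0.0527) and EGLN3 with the length trend removed (0.445).

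Marker lists of other cell types were included as a check. Leukocyte markers HLA-DRA (4.54 ± 0.40, 4 counts in Ctrl and 103 in KO over the libraries), LAPTM5 and ITGAM rose, and CD74 fell (−0.91 ± 0.14). The other 3 of the 7 were not called (3 and 1 adjusted over the list alone; camera adjusted p = 0.519). Of 12 endothelial markers ROBO4 (2.11 ± 0.21), PECAM1 (1.10 ± 0.12), CDH5 and VWF rose, and CLDN5 (−0.72 ± 0.13) fell. The other 7 were not called (4 and 1 adjusted over the list alone; camera adjusted p = 0.137). LIN28B (2.02 ± 0.54) rose, and ELAVL3 (−1.36 ± 0.22) and DPYSL3 fell. The other 4 of the 7 neural and HEK293-like markers were not called (1 and 2 adjusted over the list alone; camera adjusted p = 0.473). Each of 5 cancer-testis genes was not called (0 and 0 adjusted over the list alone; camera adjusted p = 0.938), with SSX1 at 0.85 ± 0.41. CD74, PECAM1, CLDN5, LIN28B and ELAVL3 lost their calls under ERCC scaling (adjusted p from 0.118 to 0.592), ELAVL3 without Ctrl replicate 1 (0.0528), and CLDN5 and LIN28B without Ctrl replicate 1, 2 or 3 or KO replicate 1, and LIN28B without KO replicate 3 (0.0545 to 0.158). LAPTM5, ITGAM, CDH5 and DPYSL3, named without a value, were lost under ERCC scaling (0.0525 to 0.872) and without 2 or more of the single libraries (0.0577 to 0.185), ITGAM and DPYSL3 also with no filter (0.0790 and 0.0532) and the length trend removed (0.0791 and 0.104), and DPYSL3 under library size alone (0.115). In 4sU-seq 13 of the 32 lists passed the camera threshold and 0 did so with an estimated correlation. The estimate lay below the preset of 0.01 for interferon-stimulated genes (−0.02), YAP targets (−0.05) and mesenchymal genes (−0.04). Their calls were lost too, so the loss is not by itself a sign of correlation between members. With fry 12 lists passed, including some that camera did not call (WNT targets, fry adjusted p = 0.0287). Median and test differed in sign for the P-TEFb list (median 0.01), the mitochondrially encoded genes (0.06) and the SMAD and BMP list (0.10), each tested lower, and the NRF2 targets had a median of −0.09 and a mean of 0.01.

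Steady-state RNA answered the same question for RNA as it accumulates. PPM1G fell from 326, 293 and 331 CPM in Ctrl replicates 1 to 3 to 97.9, 95.0 and 98.0 CPM in KO (log2 −1.71 ± 0.06, adjusted p = 1.77e-10), a 3.27-fold decrease. PXDN (7.96 ± 0.27, from 0.160 to 36.5 CPM) and EHF (7.44 ± 0.34, from 0.699 to 112 CPM) again rose most among genes of at least 4 CPM on average. Ctrl replicate 3 held 0.454 CPM of PXDN and 1.78 CPM of EHF, against 0.0247 and 0.222 in replicate 1 and 0 and 0.0896 in replicate 2; without it the change of EHF was 9.43 and PXDN was left with too few Ctrl counts for a fold, and over the alternatives the lowest changes of PXDN and EHF were 7.41 and 6.97. The double-stranded RNA receptor TLR3 rose by 4.32 ± 0.15, CASP4 by 4.30 ± 0.13, the keratin KRT23 by 4.17 ± 0.11, the transcription factor NFIB by 4.13 ± 0.10 and filamin C (FLNC) by 3.80 ± 0.06, from 11.4 to 158 CPM. KRT23 had no count in any 4sU-seq library. ZNF595 changed by −7.74 ± 0.22, the matrix protein tenascin C (TNC) by −6.43 ± 0.25, TNFSF4 by −6.22 ± 0.16, FGF9 by −5.52 ± 0.18, NAV3 by −4.44 ± 0.09, DACT1 by −4.42 ± 0.13, GLIS3 by −4.42 ± 0.08 and TMEM200A by −3.80 ± 0.09. The KO levels of ZNF595 (0.0366 CPM) and TNC (0.0968 CPM) lay at or below the floor of detection, so the sizes of their changes rest on few counts. TNC (ENSG00000041982) lies on chromosome 9 from 115019578 to 115118257 and TNFSF4 (ENSG00000117586) on chromosome 1 from 173183734 to 173207313.

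In RNA-seq 9871 of 20415 genes were called, 4398 higher and 5473 lower, and 1165 rose and 246 fell by more than 2-fold. Of 13653 protein-coding genes tested 8151 were called, and the counts of list members below stand against this share. The groups did not overlap for 11446 genes, 56.1% of those tested, where chance gives 10%. Among genes with a mean log2 CPM of at least 4 the median change was below 0 on every chromosome, from −0.23 on chromosome 22 to −0.08 on chromosome 8. Some list medians lie within that range, such as those of the P-TEFb (−0.15), SR protein (−0.16) and SMN (−0.20) lists. Of the calls 44.6% were higher; this was 61.6% of 7103 calls under ERCC scaling and 72.5% of 10256 under library size alone, which moved the median of all genes from 0.00 to 0.19. The labels do not describe how the cultures behind the RNA-seq replicates were made, so p-values of this assay measure the spread between these samples only, which may be technical. Calls of the genes named by the rule in RNA-seq held under each alternative that was run for single genes and kept the gene, except those of MAGEA12, RPL28 and RPL38; the fold threshold and the fit of all 12 libraries were run for the count of calls alone, which they lowered to 1837 and 4544.

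Immediate early genes were lower in steady-state RNA: 4 of 32 rose (JUNB, BTG1, BTG2 and IER5), 18 fell and 10 were not called (5 and 18 adjusted over the list alone). FOSL1 changed by −2.03 ± 0.07, ZFP36L1 by −1.97 ± 0.07, KLF4 by −1.73 ± 0.06 and the MAP kinase phosphatase DUSP4 by −1.41 ± 0.06 (list median −0.28, camera adjusted p = 7.46e-09; adjusted p = 0.761 with an estimated correlation). Interferon-stimulated genes were higher, with 22 of 28 rising, 1 falling and 5 not called (22 and 1 adjusted over the list alone). SAMD9 rose by 1.86 ± 0.07, PARP9 by 1.80 ± 0.08, the RNA sensor IFIH1 by 1.59 ± 0.10 and DTX3L by 1.11 ± 0.07. Their median was 1.01 (camera adjusted p = 3.93e-14; adjusted p = 0.166 with an estimated correlation). Of 22 NF-kB and TNF response genes 5 rose, BIRC3 (1.24 ± 0.14), TNFAIP2 (0.72 ± 0.05), ICAM1, LIF and NFKBIZ, and 8 fell, among them NFKB1 (−0.76 ± 0.06) and TNIP1 (−0.54 ± 0.06). The other 9 were not called (5 and 8 adjusted over the list alone; camera adjusted p = 0.975). For p53 targets the counts were 16 higher, 8 lower and 7 not called of 31 (16 and 8 adjusted over the list alone; camera adjusted p = 0.0973), with GDF15 at 1.34 ± 0.06, TP53INP1 at 1.20 ± 0.07 and PLK2 at −1.15 ± 0.06. That list was called higher under library size alone (adjusted p = 0.00622), with no filter (0.0380), with a mean of 50 counts or more (0.00820) and without Ctrl replicate 1 (0.0462). PPM1K (0.93 ± 0.10) and PHLPP1 (0.34 ± 0.05) were among 7 PPM family phosphatases that rose, and ILKAP (−0.41 ± 0.05), PPTC7, PPM1H and PPM1B fell. The other 7 of the 18 were not called (7 and 4 adjusted over the list alone; camera adjusted p = 0.419). Of 28 P-TEFb, 7SK snRNP and pause-release genes HEXIM2, SUPT4H1 and AFF4 rose and 15 fell, such as the elongation factor subunit SUPT5H (−0.68 ± 0.06), SUPT6H (−0.44 ± 0.06) and POLR2A (−0.41 ± 0.06). The other 10 were not called (3 and 15 adjusted over the list alone; camera adjusted p = 0.0980, and 0.0153 with no filter).

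Ribosome biogenesis genes fell almost throughout: 26 of 28 fell, GNL3 rose (0.95 ± 0.06) and 1 was not called (1 and 26 adjusted over the list alone). Examples were NOP2 (−0.67 ± 0.06), RRP12 (−0.67 ± 0.06) and BOP1 (−0.64 ± 0.05). Their median was −0.39 (camera adjusted p = 2.73e-06; adjusted p = 0.761 with an estimated correlation). G2/M and mitosis genes followed, 21 of 27 falling, 0 rising and 6 not called (1 and 21 adjusted over the list alone). UBE2C (−0.81 ± 0.06), AURKA (−0.68 ± 0.06) and the kinase PLK1 (−0.64 ± 0.06) fell, and the list median was −0.38 (camera adjusted p = 1.46e-05; adjusted p = 0.761 with an estimated correlation). Of 30 G1/S and DNA replication genes 21 fell, CCNE2 rose and 8 were not called (1 and 22 adjusted over the list alone). Cyclin E1 (CCNE1) changed by −0.50 ± 0.05, CLSPN by −0.49 ± 0.06 and RRM2 by −0.47 ± 0.06. The list median was −0.26 (camera adjusted p = 0.00470; adjusted p = 0.761 with an estimated correlation), and its call was lost with a mean of 50 counts or more (0.0640). RPS15 (−0.38 ± 0.06) and RPL18 (−0.35 ± 0.06) were among 16 cytosolic ribosomal protein genes that fell, while RPS27 and RPS12 rose. The other 40 of the 58 were not called (0 and 11 adjusted over the list alone; camera adjusted p = 0.407). RPL28 (−0.28 ± 0.06) and RPL38 (−0.26 ± 0.06) lost their calls under ERCC scaling (0.0676 and 0.113) and library size alone (0.0721 and 0.179). Histone genes numbered 19 lower, HIST2H2AA4 (−0.58 ± 0.06) among them, 3 higher, HIST1H3E (0.88 ± 0.10), HIST1H2BL (0.55 ± 0.07) and HIST1H2BG, and 21 not called of 43 (3 and 19 adjusted over the list alone; camera adjusted p = 0.0973). With no filter and without Ctrl replicate 1, Ctrl replicate 2 or KO replicate 3 that list was called lower (0.0169, 0.0462, 0.0419 and 0.0182), as it was with a replicate block (0.0489) and the length trend removed (0.0415). In the splicing lists, GEMIN8 rose and 12 of 21 SMN complex and Sm protein genes fell, such as GEMIN4 (−0.62 ± 0.05) and SNRNP70 (−0.43 ± 0.06). The other 8 were not called (1 and 12 adjusted over the list alone; camera adjusted p = 0.0888). SRPK1 (−0.62 ± 0.05) and SRSF6 (−0.40 ± 0.06) were among 12 of 22 SR proteins and kinases that fell, and CLK1 rose. The other 9 were not called (1 and 12 adjusted over the list alone; camera adjusted p = 0.0973). The SMN and SR lists were called lower with no filter (0.00716 and 0.00946), without Ctrl replicate 1 (0.0374 and 0.0391) and without KO replicate 3 (0.0254 and 0.0311), and the SMN list also with a replicate block (0.0496).

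Adhesion and identity genes showed further single changes in RNA-seq. All but 1 of 14 YAP targets fell and 0 rose (0 and 13 adjusted over the list alone), with F3 at −1.76 ± 0.06, AMOTL2 at −1.24 ± 0.06 and CYR61 at −1.24 ± 0.06 (median −0.61, camera adjusted p = 8.33e-12; adjusted p = 0.166 with an estimated correlation). VIM (−4.28 ± 0.28), ZEB1 (−1.91 ± 0.10), COL6A1 and SNAI1 fell among 12 mesenchymal genes, while TWIST1 (3.07 ± 0.24), S100A4 (1.05 ± 0.06), COL1A1 and ACTA2 rose. The other 4 were not called (6 and 4 adjusted over the list alone; camera adjusted p = 0.757). Of 21 epithelial adhesion genes 7 rose, 9 fell and 5 were not called (7 and 10 adjusted over the list alone; camera adjusted p = 0.574), TJP3 rising by 1.81 ± 0.08 and GRHL2 by 0.75 ± 0.05, and ESRP2 changing by −0.74 ± 0.06. KRT20 (2.00 ± 0.21), CEACAM1 (1.26 ± 0.25), CA2 and SLC26A3 rose among 8 intestinal differentiation genes, and CDX2 fell (−0.41 ± 0.07). The other 3 were not called (4 and 1 adjusted over the list alone; camera adjusted p = 0.156). WNT targets split into 8 higher, 5 lower and 2 not called of 15 (8 and 5 adjusted over the list alone; camera adjusted p = 0.486); EPHB2 rose by 1.63 ± 0.07 while SOX4 (−1.49 ± 0.07), SOX9 (−1.08 ± 0.06), cyclin D1 (CCND1, −0.62 ± 0.06), CD44 and TCF7 fell. SMAD and BMP response genes gave 7 higher, 7 lower and 2 not called of 16 (7 and 7 adjusted over the list alone; camera adjusted p = 0.713), ID2 rising by 2.01 ± 0.07. Within the integrin, laminin and basement membrane list ITGAV (1.05 ± 0.07), ITGA2 (0.94 ± 0.06), ITGA1, HSPG2 and LAMB1 rose and 10 of 19 fell, such as AGRN (−1.20 ± 0.07) and ITGB5 (−0.84 ± 0.06). The other 4 were not called (5 and 10 adjusted over the list alone; camera adjusted p = 0.139).

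Cholesterol synthesis genes rose in steady-state RNA, 14 of 23, with TMEM97 (−0.45 ± 0.06) falling and 8 not called (14 and 1 adjusted over the list alone). INSIG1 rose by 0.96 ± 0.07 and IDI1 by 0.84 ± 0.10 (median 0.23, camera adjusted p = 0.00436; adjusted p = 0.761 with an estimated correlation). Mitochondrially encoded genes fell, 12 of 15, with 0 rising and 3 not called (0 and 12 adjusted over the list alone). MT-CO1 stood at −0.71 ± 0.08 and MT-ND1 at −0.58 ± 0.08, and the list median was −0.43 (camera adjusted p = 0.00470, and adjusted p = 0.761 with an estimated correlation). Their share of counts was 1.39% and 1.35% in KO replicates 1 and 2 but 1.65% in KO replicate 3, near the 1.71% of Ctrl replicate 3. Heat shock genes fell as well, 11 of 14 with 0 rising and 3 not called (0 and 11 adjusted over the list alone): BAG3 stood at −0.90 ± 0.07, HSPA1A at −0.87 ± 0.07 and DNAJB1 at −0.61 ± 0.06 (median −0.32, camera adjusted p = 0.00139; adjusted p = 0.761 with an estimated correlation). ATF4 and amino acid stress genes divided into 11 higher, 8 lower and 5 not called of 24 (11 and 9 adjusted over the list alone; camera adjusted p = 0.660), with DDIT4 at 1.08 ± 0.07, the amino acid transporter SLC7A5 at −0.54 ± 0.05 and STC2 at −0.50 ± 0.06. In the unfolded protein response list EDEM1, DNAJB9 and HERPUD1 rose and 9 of 16 fell, among them MANF (−0.44 ± 0.06) and CALR (−0.31 ± 0.06). The other 4 were not called (3 and 9 adjusted over the list alone; camera adjusted p = 0.359). Hypoxia and glycolysis genes counted 11 higher, 6 lower and 4 not called of 21 (11 and 6 adjusted over the list alone; camera adjusted p = 0.230), PDK1 at 0.80 ± 0.06 and HK2 at −0.72 ± 0.05. For NRF2 targets 12 of 19 fell, GCLM (−0.82 ± 0.08) and OSGIN1 (−0.67 ± 0.07) among them, while AKR1C3 and AKR1C2 rose. The other 5 were not called (2 and 12 adjusted over the list alone; camera adjusted p = 0.0973). This list was called lower with no filter (0.00899) and without Ctrl replicate 1 (0.0440). Apoptosis regulators gave 5 higher (BIRC2 at 0.50 ± 0.07, PMAIP1, BAK1, CASP8 and XIAP), 9 lower (BIK at −0.93 ± 0.07, BCL2L1 at −0.54 ± 0.06) and 6 not called of 20 (5 and 9 adjusted over the list alone; camera adjusted p = 0.489).

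Markers of other cell types were few in RNA-seq. MAGEA12 fell (−0.79 ± 0.28) and 5 of 6 cancer-testis genes were not called (0 and 0 adjusted over the list alone; camera adjusted p = 0.926); the call of MAGEA12 was lost under ERCC scaling, library size alone, no filter and the DESeq2 Wald test (adjusted p from 0.0626 to 0.189) and without Ctrl replicate 1, 2 or 3 or KO replicate 1 or 3 (0.0501 to 0.118) and with KO replicates 1 and 2 added into 1 library (0.0543). HLA-DRA (3.59 ± 0.39, 5 counts in Ctrl and 66 in KO over the libraries) and CORO1A rose. The other 2 of the 4 leukocyte markers were not called (2 and 0 adjusted over the list alone). Of the neural markers DPYSL3 (−0.45 ± 0.06) fell and SYP rose. The other 2 of the 4 were not called (1 and 2 adjusted over the list alone). Neither of the 2 endothelial markers tested was called (0 and 0 adjusted over the list alone), CLDN5 standing at 0.55 ± 0.26 (called without KO replicate 3, 0.0462, and under library size alone, 0.0380). These 3 lists had too few tested members for camera. In RNA-seq 9 lists passed the camera threshold, 0 did so with an estimated correlation and 14 passed without Ctrl replicate 1. Median and test differed in sign for the epithelial adhesion genes (median −0.12) and the SMAD and BMP list (−0.10), both tested higher, the p53 targets had a median of 0.17 and a mean of −0.03, and the NF-kB list had a median of −0.02 and a mean of 0.05.

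**Figure D2:**
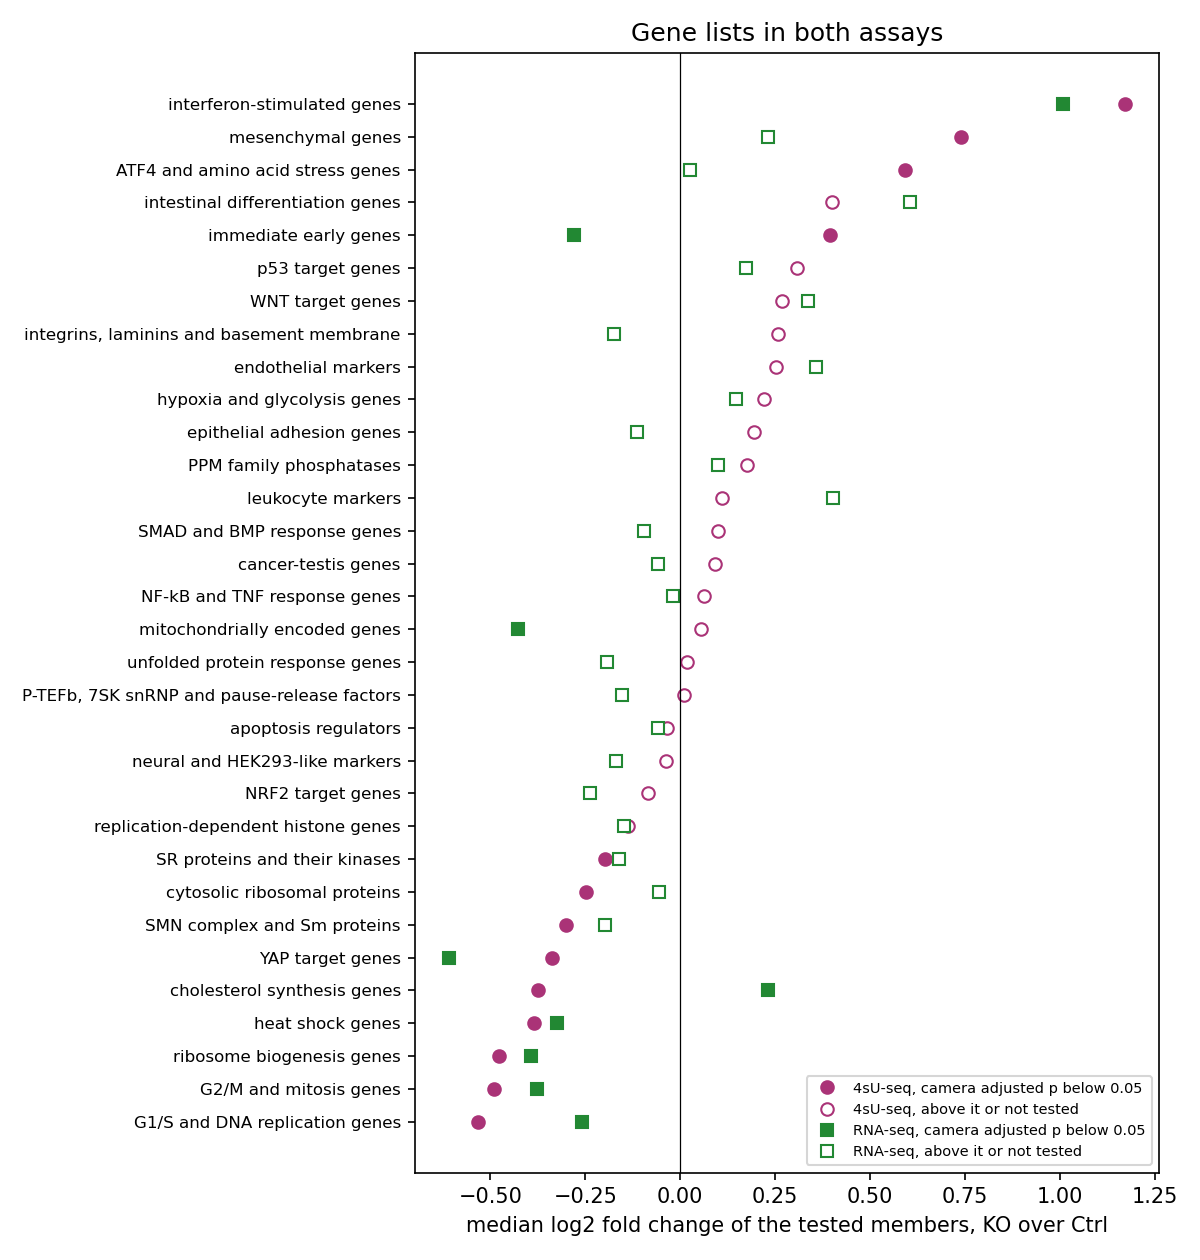
Median log2 fold change (KO over Ctrl) of the tested members of each of the 32 gene lists in 4sU-seq (circles) and RNA-seq (squares); filled symbols had a camera adjusted p below 0.05. Interferon-stimulated genes lie at 1.17 and 1.01; the SR protein list at −0.20 in 4sU-seq turns to 0.06 under ERCC scaling, and filled symbols are open with an estimated correlation in both assays.

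Nascent and steady-state changes were then compared gene by gene. Of protein-coding genes with coordinates and at least 10 CPM in RNA-seq, 346 (3.75%) had no count in any 4sU-seq library, and the labels do not say whether both assays were counted with the same settings. Immediate early transcription factors differed most among called genes with a mean log2 CPM of at least 2 in both assays. These were EGR1 (4sU-seq minus RNA-seq 3.35 ± 0.17, adjusted p = 7.63e-06), FOS (3.09 ± 0.27, 0.000792) and JUN (2.72 ± 0.23, 0.000792). Each rose in nascent RNA, while in steady-state RNA EGR1 stood at −0.12, FOS at −0.28 and JUN at −0.87. TNFSF4 fell less in nascent RNA (difference 2.50 ± 0.34, adjusted p = 0.00568). MMP14, a membrane-bound matrix metalloproteinase, changed by 1.68 in 4sU-seq and 3.62 in RNA-seq (−1.95 ± 0.27, adjusted p = 0.00596) and GGT1, a gamma-glutamyltransferase, by 2.17 and 3.62 (−1.46 ± 0.30, 0.0308). IDI1 went opposite ways, at −0.61 in 4sU-seq and 0.84 in RNA-seq (difference −1.44 ± 0.21, adjusted p = 0.00834). PPM1G differed by 0.59 between the assays with adjusted p = 0.0850. Differences of TNFSF4, GGT1 and IDI1 were lost under ERCC scaling (0.455, 0.401 and 1.00), and that of GGT1 without each of the libraries except KO replicate 2 of 4sU-seq (0.0540 to 0.0975).

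Of 15863 genes tested for a difference between the assays 397 were called, 199 higher and 198 lower in 4sU-seq, and 2581 had an unadjusted p below 0.05. The share higher, 50.1%, was 27.6% under library size alone, 32.5% with TMM over all 12 libraries and 71.4% of the 7 calls left under ERCC scaling, which moved the median of all genes to 0.14. The count was 4364 without 4sU-seq KO replicate 2 and 129, 155, 131 and 145 without Ctrl replicates 1, 2 and 3 and KO replicate 1 of 4sU-seq, and 171, 226, 161, 122, 86 and 134 without Ctrl replicates 1, 2 and 3 and KO replicates 1, 2 and 3 of RNA-seq. Across the 15863 genes the log2 fold changes of the assays had a Pearson r of 0.81 and a Spearman rho of 0.66, and 73.2% shared their sign; genes are not independent replicates. Of the genes called in both, 1293 were higher in both and 885 lower in both, where independent lists would share 369 and 405. Opposite calls numbered 20 and 19, where independent lists would share 496 and 302.

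**Figure D3:**
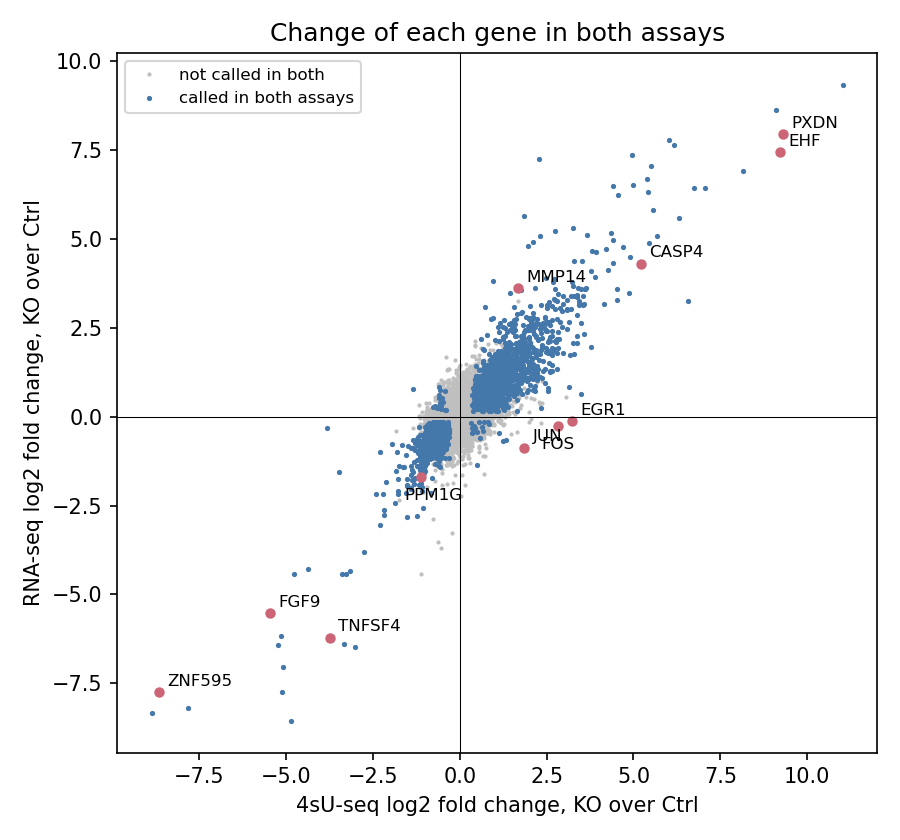
Log2 fold change (KO over Ctrl) of each gene in 4sU-seq (horizontal axis) against RNA-seq (vertical axis); blue points were called in both assays and red points are genes named in the text. PXDN and EHF lie at the upper right, ZNF595 at the lower left, and EGR1 and FOS lie at 3.23 and 2.82 in 4sU-seq with RNA-seq values of −0.12 and −0.28.

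Gene groups differed between the assays too. For immediate early genes 15 of 29 were higher in 4sU-seq than in RNA-seq, 0 lower and 14 not called (22 and 0 adjusted over the list alone). They had a median difference of 0.87 (camera adjusted p = 5.58e-39; adjusted p = 0.0467 with an estimated correlation). ATF4 and amino acid stress genes had 8 of 22 higher. The other 14 were not called (14 and 0 adjusted over the list alone; median 0.64, adjusted p = 1.65e-17; adjusted p = 0.0308 with an estimated correlation). Cholesterol synthesis genes had 7 of 22 lower in 4sU-seq. The other 15 were not called (0 and 12 adjusted over the list alone; median −0.52, adjusted p = 1.03e-17; adjusted p = 0.0308 with an estimated correlation). Among integrins, laminins and basement membrane genes COL17A1 was higher. The other 17 of the 18 were not called (10 and 0 adjusted over the list alone; median 0.44, adjusted p = 6.74e-06; adjusted p = 0.0226 with an estimated correlation). These 4 list calls held with an estimated correlation, and 7 others did not. Mitochondrially encoded genes had a median difference of 0.45, with 0 of 15 called (11 and 0 adjusted over the list alone; adjusted p = 2.79e-08; adjusted p = 0.318 with an estimated correlation). YAP targets stood at 0.32, with CYR61 called (3 and 0 adjusted over the list alone; adjusted p = 0.00262; adjusted p = 0.0609 with an estimated correlation). Of 28 p53 targets 6 were higher, GDF15 among them. The other 22 were not called (6 and 1 adjusted over the list alone; median 0.20, adjusted p = 0.00383; adjusted p = 0.102 with an estimated correlation). G1/S and DNA replication genes stood at −0.30, with GINS1 called (0 and 8 adjusted over the list alone; adjusted p = 1.22e-08; adjusted p = 0.262 with an estimated correlation), and cytosolic ribosomal proteins at −0.13, with RPS24 and RPL37 called (0 and 3 adjusted over the list alone; adjusted p = 3.62e-05; adjusted p = 0.642 with an estimated correlation). The epithelial adhesion list had CDH1 called (1 and 0 adjusted over the list alone; median 0.19, adjusted p = 0.00405; adjusted p = 0.468 with an estimated correlation) and the P-TEFb list 0 of 26 (0 and 0 adjusted over the list alone; median 0.16, adjusted p = 0.0132; adjusted p = 0.262 with an estimated correlation). Without 4sU-seq KO replicate 2 the calls of the P-TEFb (0.127), epithelial (0.316) and p53 (0.0993) lists were lost, the first 2 also with both 4sU-seq replicates numbered 2 left out (0.0550 and 0.0887).

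Other lists did not differ between the assays at an adjusted p of 0.05. NF-kB and TNF response genes gave adjusted p = 0.102, interferon-stimulated genes 0.463, G2/M and mitosis genes 0.199, ribosome biogenesis genes 0.317, replication-dependent histone genes 0.423, SMN complex and Sm proteins 0.198, SR proteins 0.949, heat shock genes 0.981 and NRF2 targets 0.794, each with 0 members called (0 adjusted over the list alone for each of these). PPM family phosphatases gave 0.949 with PDP1 called (1 and 0 adjusted over the list alone), WNT targets 0.310 with CD44 and DKK1 called (2 and 1 adjusted over the list alone), mesenchymal genes 0.875 with TWIST1 called (0 and 1 adjusted over the list alone) and intestinal genes 0.185 with MUC13 called (1 and 0 adjusted over the list alone). The unfolded protein response list gave 0.0579 with HERPUD1 called (1 and 0 adjusted over the list alone), hypoxia and glycolysis genes 0.273 with NDRG1 called (1 and 0 adjusted over the list alone), SMAD and BMP genes 0.293 with 1 called (2 and 0 adjusted over the list alone) and apoptosis regulators 0.483 with MCL1 called (2 and 0 adjusted over the list alone). Leaving out single libraries brought past the threshold the NF-kB list (4sU-seq Ctrl replicate 2, 0.0269; KO replicate 3, 0.0214), the histone list (4sU-seq KO replicate 1, 0.0367; KO replicate 3, 0.0214; and with the sign turned to −0.19 KO replicate 2, 0.0198), the ribosome biogenesis list (4sU-seq KO replicate 2, 0.0117), the hypoxia list (4sU-seq KO replicate 3, 0.0433) and the SMN list (RNA-seq Ctrl replicate 3, 0.0338). The unfolded protein response list passed without 4sU-seq Ctrl replicate 2 (0.0217), KO replicate 1 (0.00912) or KO replicate 3 (0.0214) and without RNA-seq Ctrl replicate 1 (0.0323) or KO replicate 3 (0.0431). It also passed with a replicate block (0.0495) and the length trend removed (0.00639), as did the NF-kB list (0.0461 and 0.0476, and 0.0243 under ERCC scaling), and the ribosome biogenesis list passed with both 4sU-seq replicates numbered 2 left out (0.0185). Cancer-testis, leukocyte, endothelial and neural markers had too few members for the test, with CLDN5 alone called (0 and 1 adjusted over the list alone of endothelial markers).

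Chromosomes were compared by the median change of their genes, to see whether whole chromosomes stood apart. Medians ran from −0.07 on chromosome 19 to 0.17 on chromosome 8 in 4sU-seq and from −0.07 on chromosome 20 to 0.05 on chromosome 8 in RNA-seq. Among genes with a mean log2 CPM of at least 4 the 4sU-seq medians ran from −0.22 on chromosome 21 to 0.01 on chromosome 18. The medians of both assays were given as description, with no test between replicates.

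**Figure D4:**
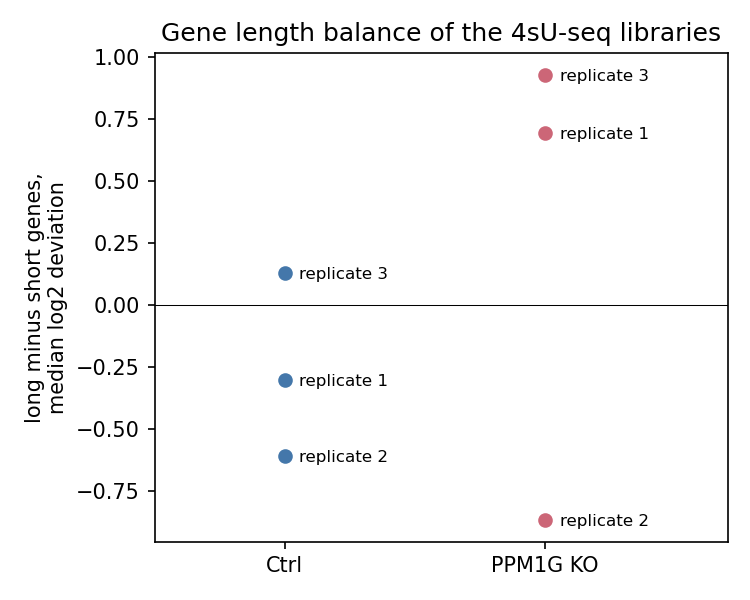
Median log2 deviation of 427 genes above 300 kb minus that of 1527 genes under 10 kb in each 4sU-seq library, relative to the mean of the libraries, for Ctrl and KO. KO replicate 2 lies at −0.87 and KO replicates 1 and 3 at 0.70 and 0.93, while the Ctrl libraries lie between −0.61 and 0.13.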

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

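Tests chosen only after the result was seen are those of library differences within the groups, of carry-over of KO RNA into RNA-seq Ctrl replicate 3, and each value given with the length trend removed or the replicates numbered 2 left out. The genes and lists of the next 2 paragraphs stood out because the change from Ctrl to KO differed between 4sU-seq and RNA-seq by the interaction test; the gene length gradient and the large changes shared by both assays were taken up from the values seen.

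Differences between assays were called for 397 genes. Of 100 splits drawn, 9 gave as many genes, the real one included, and 32 gave at least the real number of 11 lists; the highest other values were 2752 genes and 16 lists. The draw with 2752 genes mixed the 4sU-seq labels but kept those of RNA-seq, and those with 16 lists kept the 4sU-seq labels, so they held a real genotype contrast. Of the 85 draws with mixed labels in both assays 7 gave as many genes, with 1041 the highest, and 19 as many lists, so chance is not excluded for either count. List medians (4sU-seq minus RNA-seq) past the threshold were 0.16 for P-TEFb and pause-release genes, 0.20 for p53 targets, −0.30 for G1/S and DNA replication genes, −0.13 for cytosolic ribosomal proteins, 0.19 for epithelial adhesion genes, 0.45 for mitochondrially encoded genes, 0.32 for YAP targets and 0.44 for integrins, laminins and basement membrane. TNFSF4 differed by 2.50, MMP14 by −1.95, GGT1 by −1.46 and IDI1 by −1.44.

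Immediate early genes (median 0.87; EGR1 3.35, FOS 3.09, JUN 2.72), ATF4 and amino acid stress genes (0.64) and cholesterol synthesis genes (−0.52) differed most between the assays among the lists with at least 5 tested members. With the gene length trend of each library removed the medians were 0.90, 0.65 and −0.47, which argues against that trend as the whole cause. Over the 12 fits without 1 library the values nearest 0 were 0.75, 0.57 and −0.42, which argues against a single library. A difference of the genotypes in RNA synthesis against stability may contribute but was not tested. Different cultures, handling or counting settings for the assays also stay open, since the labels do not say whether both assays came from the same dishes or were counted alike.

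The change in 4sU-seq rose with gene length, most in KO replicates 1 and 3. The lowest Spearman rho over the 6 fits without 1 library was 0.0117 (without KO replicate 3) and rho was 0.36 without KO replicate 2, so the gradient in the group comparison rests on single libraries. The gap between long and short genes spanned 1.79 among the KO libraries and 0.74 among the Ctrl libraries, against a difference of group means of 0.51 (two-sided exact permutation p = 0.4, where 0.1 is the smallest possible), which is consistent with library differences within the groups. Carry-over of mature RNA in KO replicate 2 gave a mean rho of −0.0364 over 4 gene span classes, with class values from −0.28 to 0.13; it cannot be told apart from no carry-over because the classes differ in sign. A slower or faster polymerase in KO cells, the biological reading, was not tested and stays open, as does a difference between sequencing runs, which the labels do not give.

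Several protein-coding genes of at least 1 CPM on average in RNA-seq were called with changes of more than 3 (log2) in both assays: 12 were lower in KO, such as ZNF595, FGF9, TNC, TNFSF4 and VIM, and 26 were higher, such as PXDN, EHF, TLR3 and CASP4. The nearest tested neighbours had a median RNA-seq change of −0.22 (95% bootstrap interval −0.59 to −0.00) beside the genes lower in KO and 0.17 (0.02 to 0.33) beside those higher in KO, against −0.05 for all genes; a lost segment cannot be told apart from none because its interval reaches both the bound set for it and the bound set against it, nor can a gained one, whose interval stays below the bound set for it while 22% of the neighbours rose by more than 1 (log2) against 5.77% of all genes. Over 7 genes chosen from the 4sU-seq libraries, RNA-seq Ctrl replicate 3 held a median of 1.59% of the KO level, against 0.0676% and 0% in replicates 1 and 2; carry-over of KO RNA cannot be told apart from none, because the ratio of 3.37 between the quartiles lies between the bounds set for and against a single share and 7 genes are few (12 genes chosen earlier for being low in replicates 1 and 2, with limits relaxed after 4 settings had been viewed, gave 1.93%, but that choice favours replicate 3 by its construction). For PXDN and EHF this library supplied most of the Ctrl signal (1.24% and 1.59% of the KO level, against 0.0676% and 0.198% in replicate 1), and without it the RNA-seq change of EHF moved from 7.44 to 9.43. Differences between cell clones, epigenetic switching and an effect of PPM1G loss stay open, as the labels do not say whether the KO cells are a clone, and no biological explanation was tested.

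Within 4sU-seq, 1 of the 10 splits of the 6 libraries, the real one, gave 4166 genes and the highest other gave 1178; 3 splits gave as many lists as the real 13, the highest other 15. The split with 1178 genes set Ctrl replicates 1 and 2 and KO replicate 2, the 3 libraries with the lowest values of long against short genes, against the rest. In RNA-seq 1 of the 10 splits, the real one, gave 9871 genes, with 5 the highest of the others, and 7 splits gave at least the real 9 lists, with 13 the highest other. With 10 splits no share under 0.05 can be reached in either assay.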

How the results depend on the processing

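Alternatives chosen after seeing the data were the length trend removed, the replicates numbered 2 left out and RNA-seq KO replicates 1 and 2 added into 1 library. Directions of the named genes did not reverse: of 1815 values in 4sU-seq 1484 kept their side of the threshold and 331 lost it, of 1982 in RNA-seq 1966 kept it, 14 lost and 2 gained it, and of 168 between assays 153 kept and 15 lost it. Of list results, judged by camera, 460 of 480 in 4sU-seq, 427 of 448 in RNA-seq and 648 of 672 between assays kept their side. In RNA-seq and between assays these include lists with too few tested members for camera, which counted as kept. The estimated correlation and fry are not part of these counts. Camera compares a list with the other genes, so alternatives that rescale all genes of a library together could hardly change its result.

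The 4sU-seq count of 4166 was 716 under ERCC scaling, where PPM1G stood at −0.93 (adjusted p = 0.196, against 7.87e-07 to 0.196 over its alternatives), 6922 with all 12 libraries in 1 fit, 1496 with a fold threshold of 0.5, 2493 with replicate 1 against 2 and 3 as a block, 10893 with both replicates numbered 2 left out and 1322 to 11673 without 1 library. The RNA-seq count of 9871 was 4544 with all 12 libraries in 1 fit and 1837 with the fold threshold. The count of 397 between assays was 7 under ERCC scaling, 190 with no filter, 615 with the length trend removed, 3927 with both 4sU-seq replicates numbered 2 left out and 86 to 4364 without 1 library. The correlation of 0.81 was 0.48 with no filter and 0.76 to 0.81 without 1 library. List calls were 0 in 4sU-seq, 0 in RNA-seq and 4 between assays with an estimated correlation, and 12, 21 and 9 with fry. In RNA-seq they were 15 with no filter and 9 to 14 without 1 library. The median difference of the histone list, not called at 0.06, turned to −0.19 (adjusted p = 0.0198) without 4sU-seq KO replicate 2 and ran up to 0.22 without KO replicate 3. The lower count with a fold threshold follows from its construction; for the others the cause was not tested.

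Correlations were taken between Ctrl and KO replicates of the same number, on deviations from the group means. They were −0.30, 0.95 and 0.92 in 4sU-seq and 0.14, −0.02 and 0.33 in RNA-seq. Replicates with the same number were not more alike in every case, so the libraries were not treated as pairs. In 4sU-seq the deviations fell with gene span in Ctrl replicates 1 and 2 and KO replicate 2 and rose with it in the others. This split is uneven between the genotypes, so it is partly mixed with the 4sU-seq comparison. With a replicate block 6907 genes were called in 4sU-seq and 657 between assays. On simulated data 0% of 1.5-fold changes were recovered in 4sU-seq and 83.6% in RNA-seq. The 4sU-seq libraries were the deeper ones, but their spread was larger (common coefficient of variation 0.215 against 0.0719). The simulated counts were drawn independently for each gene and library, so the shares need not hold for the real libraries. There 2011 of the 4166 genes called in 4sU-seq changed by more than 2-fold, so smaller changes were called as well.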

Other observations

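The genes named here outside the rule, and the fit with RNA-seq KO replicates 1 and 2 added into 1 library, were chosen after the values were seen. Genes called and lower by more than 3 (log2) in both assays also included DRD1, the dopamine D1 receptor, and CAPN6, a calpain family member, at −7.05 and −6.16 in RNA-seq and −5.08 and −5.13 in 4sU-seq. Their RNA-seq means in KO, 0.0586 and 0.0457 CPM, lay below the floor of detection, so the sizes of these RNA-seq changes rest on few counts. Among those that rose by as much were the protease inhibitor SLPI (3.17 in RNA-seq, 3.46 in 4sU-seq), the kinase SYK (3.60 and 3.62), the peptidase DPP4 (3.39 and 3.29) and the G protein regulator RGS2, which rose from 4.62 to 41.5 CPM in RNA-seq.

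Of protein-coding genes with coordinates and at least 10 CPM in RNA-seq, 346 (3.75%) had no count in any 4sU-seq library, and 99.7% of these overlap another annotated gene, against 67.8% of the 8876 that were counted. In the other direction 16 genes above 10 CPM in 4sU-seq had no count in RNA-seq. Whether both tables were counted with the same settings is not given in the sources used here. RNA-seq KO replicates 1 and 2 differed from each other by 1.71 chi-square units per degree of freedom, against 10.5 or more for the other pairs of RNA-seq libraries of 1 group, and were kept as separate libraries. The labels do not say whether they come from separate cultures; added into 1 library, which leaves 2 KO libraries, they gave 8512 called genes against 9871. The share of counts from mitochondrially encoded genes was 1.71 to 1.91% in Ctrl and 1.35 to 1.65% in KO of RNA-seq.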
